A study of Homo sapiens with 12 samples.

How the data were processed

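RNA was measured in 12 tumour libraries, 6 from control and 6 from RING1B knock-down xenografts of SK-ES1, an established Ewing sarcoma cell line. A xenograft is a tumour grown from these human cells in a host animal of another species, which the labels do not name. RNA was extracted with an RNeasy kit and libraries were made with the TruSeq stranded mRNA kit, which selects polyadenylated RNA and keeps strand, per the labels' protocols. The labels call the controls wild-type and state neither the silencing construct nor a control construct.

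The data are 1 table of raw read counts per gene, deposited by the authors without normalisation. Per the submitters' processing notes, the tools were FastQC, STAR 2.6.0a for alignment to hg38, featureCounts for counting, limma 3.40.2 and R 3.6.0. The strand setting of the counting, the treatment of reads that align to several places and any removal of reads from the host are not given in the sources used here. The table held 57169 genes, and for each of them both the name and the set of exons were those of GENCODE release 29, so coordinates here are on hg38 from that release. Of these names, 219 stand for several genes of the annotation and are not used for conclusions about 1 locus. A count was present in at least 1 library for 38262 genes. Host reads that align to human genes would be counted with the tumour reads, and without a stated strand setting the reads of a gene and of an overlapping antisense gene cannot be told apart.

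Total counts ranged from 23859184 to 26678325 per library, and 3 counts corresponded to 0.112 to 0.126 CPM, the counts scaled to a common library total. Libraries had counts in 24918 to 27456 genes. Every pair of libraries in a group was compared by a chi-square over genes with at least 20 summed counts. The lowest value per degree of freedom was 12.05, between control 1 and control 2, so no library was a repeat of another of its group. Library titles carry a number and a letter. The 12 libraries hold 8 numbers, 4 of them on 2 libraries each, and no number occurs in both groups. The labels do not say what the numbers and letters mark or whether the libraries come from separate animals, so p-values measure the spread between these samples. All columns of counts were used.

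Counts were analysed in R 4.3.3. Genes were kept by the filterByExpr function of edgeR 4.0.16, which left 16519 genes holding at least 99.72% of the counts, and scaled by the trimmed mean of M values (TMM), with factors from 0.921 to 1.04. Knock-down was tested against control by edgeR's quasi-likelihood F test with robust fits, with no covariate. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors of log2 fold changes were derived from the F statistic. CPM values are scaled by the TMM factors and given as mean ± SD over 6 libraries, and log2 CPM has a prior count of 2. Single values were compared by a two-sided exact permutation test over the 924 ways to divide the libraries into 6 and 6, for which the smallest p is 0.00216.

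Genes named in the text followed a rule fixed before the data were examined. It took RNF2, the gene of RING1B, then the 12 largest rises and 12 largest falls among called protein-coding genes with a mean CPM of at least 1 and no overlap between the groups, then up to 4 members of each gene list with the smallest adjusted p, then 11 genes with a role in the study. Genes outside the rule are said to be so. The 32 gene lists were written before the data were examined. They were EWSR1-FLI1 activated and repressed targets, PRC1 and PRC2 subunits, HOX genes, Polycomb-marked developmental transcription factors, G2/M phase, DNA replication and S phase, p53 targets, hypoxia response, glycolysis, cholesterol synthesis, unfolded protein and ATF4 response, interferon response, MHC class I antigen presentation, extracellular matrix, axon guidance and neuronal genes, angiogenesis, the IGF pathway, apoptosis regulators, immediate early genes, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear genes of oxidative phosphorylation, replication-dependent histones, and 7 lists of host cell markers for endothelium, macrophages and leukocytes, fibroblasts and pericytes, skeletal muscle, adipocytes, keratinocytes and blood. Of 866 list entries 864 were found, 28 of them under an older symbol. Lists with at least 3 tested members, 31 in all, were tested by camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, again with an estimated correlation, and by fry. The genes of each chromosome were tested the same way.

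Alternatives were RLE and upper quartile factors, library size alone, no low-count filter, a CPM of at least 1 in 6 libraries, DESeq2 1.42.0, limma-voom without and with sample quality weights, the title number as a random effect, counts summed by title number, the title letter or the mean of the host markers as a covariate, 1 surrogate variable from sva 3.50.0, an adjusted p of 0.01, and each library left out. Added after the data were seen were fits without 3 libraries that stood apart, without mitochondrially encoded genes, and without genes carrying a heptamer in the 3′ untranslated region (UTR). The real grouping was set beside 99 other splits of the libraries into 6 and 6, drawn with a fixed seed.

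The test was tried on simulated counts for this comparison over 16519 genes, with 50 genes changed at each of 4 fold sizes. It called 28% of the genes changed 1.5-fold, 66% of those changed 2-fold, 84% at 3-fold and 92% at 4-fold. Of 147 calls in that simulation 12 were unchanged genes. Camera called 10 of 10 sets of 25 genes shifted by 0.5 on the log2 scale and 0 of 40 unshifted sets, in simulated data without correlation between genes.

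A scan for short sequences was made after the data were seen, without a sequence named in advance, and heptamers (7 bases) were its only length. Heptamers were counted in the longest annotated 3′ UTR of 13183 tested coding genes. For each of 16256 heptamers present in at least 50 genes, the signed test statistic of the genes was regressed on its presence with 3′ UTR length and GC content as covariates, and the t of that regression was used to rank heptamers. It describes genes, which are not independent replicates, so it was judged against the other splits of the libraries. With a heptamer planted at random as a shift in shuffled statistics, the planted heptamer ranked first in 20 of 20 trials.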

Results

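The series asked what loss of RING1B does to the transcriptome of Ewing sarcoma grown as a tumour. RING1B, encoded by RNF2, is an E3 ubiquitin ligase of Polycomb repressive complex 1 (PRC1), which places ubiquitin on histone H2A. Ewing sarcoma cells carry the fusion transcription factor EWSR1-FLI1. Gene counts were obtained from 12 SK-ES1 xenograft tumour libraries, 6 control and 6 RING1B knock-down, with total counts from 23859184 to 26678325.

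RNF2 was lower in each of the 6 knock-down libraries than in any control library. The gene lies on chromosome 1 from 185045364 to 185102608 (hg38, plus strand). Its level was 47.6 ± 8.44 CPM (SD, n = 6) in control and 17.7 ± 4.56 CPM (SD, n = 6) in knock-down. Control libraries lay between 37.5 and 57.9 CPM and knock-down libraries between 12.4 and 23.4 CPM. The log2 fold change was −1.43 (SE 0.174, edgeR adjusted p = 0.00347), and the exact permutation test gave p = 0.00216, the smallest that 6 against 6 libraries can give. On the fitted scale 37.2% of the control level remained, with a 95% interval from 29.4% to 47.1%. RING1, the paralogue of RNF2, was at 60.6 ± 6.68 CPM in control and 58.9 ± 2.10 CPM in knock-down (SD, n = 6, log2 fold change −0.04, edgeR adjusted p = 0.896).

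**Figure D1:**
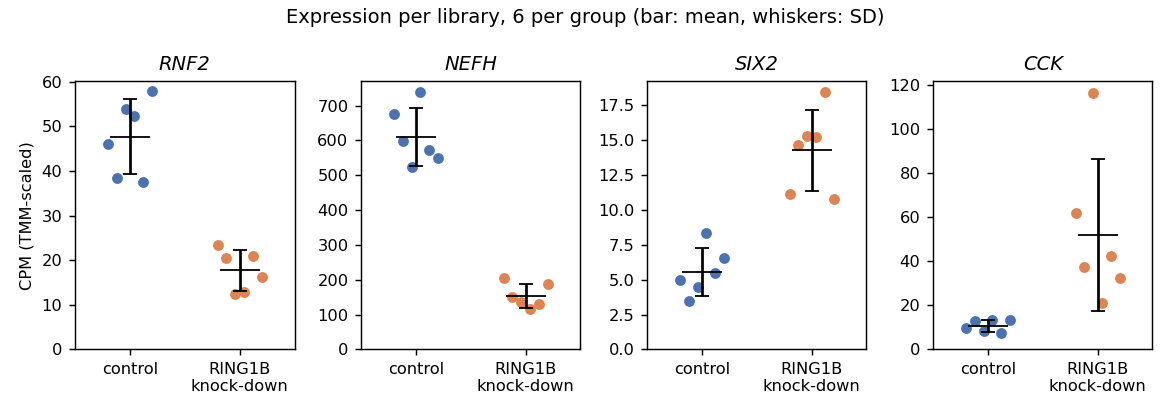
CPM (y axis, linear from 0) of RNF2, NEFH, SIX2 and CCK in each of 6 control and 6 RING1B knock-down libraries; points are libraries, the bar is the mean and the whiskers are the SD. In all 4 genes the groups do not overlap, and the 6 knock-down libraries of RNF2 lie at or below 23.4 CPM against at least 37.5 CPM in control.

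NEFH, the heavy neurofilament subunit, fell from 609.5 ± 82.4 CPM to 154 ± 34.7 CPM (SD, n = 6). This 3.95-fold fall had the lowest edgeR adjusted p of all genes (log2 fold change −1.98, SE 0.146, edgeR adjusted p = 1.36e-05). AAGAB, a protein that assists assembly of clathrin adaptors, fell 1.84-fold from 74.2 ± 7.98 to 40.3 ± 3.64 CPM (edgeR adjusted p = 0.00212). Among the rises, SIX2, a homeobox transcription factor of nephron progenitors, rose 2.57-fold from 5.54 ± 1.70 to 14.3 ± 2.90 CPM (SD, n = 6, edgeR adjusted p = 0.0113).

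In all, edgeR called 49 of 16519 genes, 29 higher and 20 lower in knock-down, and 18 of the rises and 7 of the falls were at least 2-fold. Protein-coding genes made up 46 of the 49. The largest rises of coding genes without overlap and with a mean of at least 1 CPM were those of CCK, the neuropeptide cholecystokinin (4.79-fold, log2 fold change 2.26), and FABP6, an ileal bile acid binding protein (4.56-fold, 2.19). CD200R1, the receptor of CD200 (1.81), TDRD10 (1.78) and LDOC1 (1.77) rose from levels near 1 CPM or below. TNNT1, slow skeletal muscle troponin T (1.24), COTL1, which binds actin (1.20), the extended synaptotagmin ESYT3 (1.18), the tetraspanin TSPAN11 (1.17), the neuronal pentraxin NPTX2 (1.14) and the calcium channel RYR1 (1.05) completed the 12 largest. DGAT2, an enzyme of triacylglycerol synthesis, had the largest fitted rise of all called genes (log2 fold change 3.05), but its groups overlapped and it was chosen after its values were seen.

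Among called falls without overlap between the groups and with a mean of at least 1 CPM, those that followed NEFH were DGKK, a diacylglycerol kinase (log2 fold change −1.50), TNFRSF4, the receptor OX40 (−1.46), and CORO2A, an actin-binding coronin (−1.07). FZD6, a Wnt receptor (−0.91), MAD2L1, a spindle checkpoint protein (−0.90), CD83 (−0.89), BMPR2, a BMP receptor (−0.88), SUSD5 (−0.83), the mitotic kinesin KIF15 (−0.82) and the ceramide synthase CERS5 (−0.78) fell less. CDH20 and IGFN1, chosen after their values were seen, had log2 fold changes of −1.55 and −1.51 at mean levels of 0.621 and 0.586 CPM. The adjusted p values of these falls from DGKK to CERS5 lay between 0.0113 and 0.0303 by edgeR. In 6 of the 12 largest of these separated falls, namely FZD6, MAD2L1, CD83, BMPR2, KIF15 and CERS5, the annotated 3′ UTR holds the heptamer GAAGCAA, as does that of CCK among the 12 largest separated rises. CDH20 and IGFN1 do not carry it there. GAAGCAA was picked as the heptamer with the lowest t on these same genes and libraries. Of coding genes not called lower, 13.8% carry it.

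**Figure D2:**
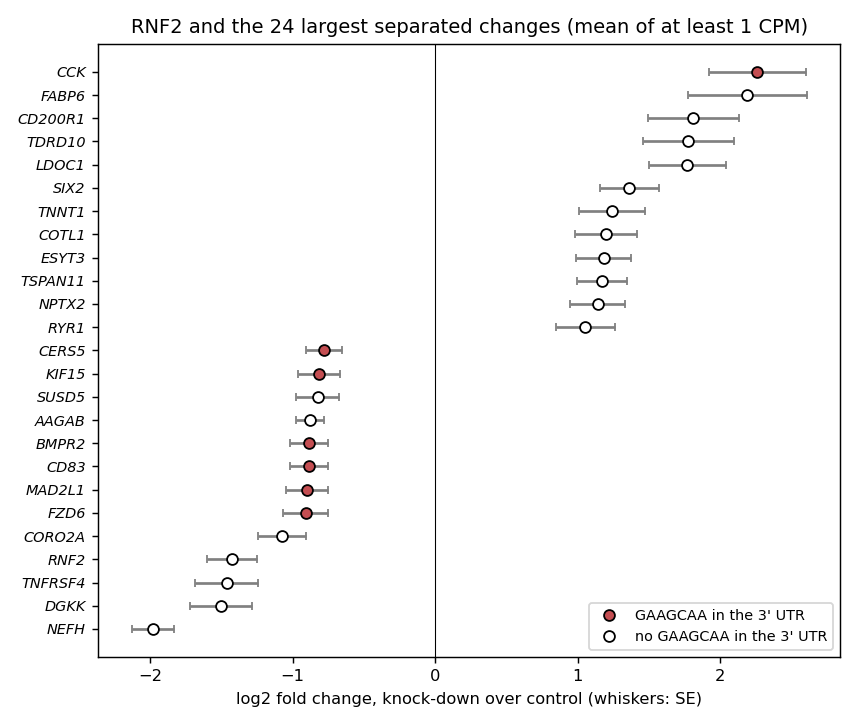
Log2 fold change in knock-down over control (x axis, whiskers are the SE) of RNF2 and the 12 largest rises and 12 largest falls among called coding genes with a mean of at least 1 CPM whose groups do not overlap. Filled points are genes with GAAGCAA in the annotated 3′ UTR, 6 of the 12 falls and 1 of the 12 rises. The heptamer was picked on these same genes and libraries, and 13.8% of coding genes not called lower carry it.

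The groups did not overlap in 202 genes, 107 higher and 95 lower, and 42 of the 49 called genes were among them. Chance gives 35.8 genes (0.216%) if the 12 libraries are independent, which is not known, since 4 title numbers are on 2 libraries each. How far that number varies over other splits was not tested. Leaving out each library in turn kept 12 calls throughout, among them those of RNF2, NEFH, AAGAB, G3BP1, DGKK, CD83, TSPAN11, BMPR2, SIX2, TNFRSF4 and LDOC1. The other 37 genes lost their call without at least 1 library, and all 49 kept their sign in each leave-out. CCK and CORO2A lost it without control 3 alone (edgeR adjusted p = 0.0523 and 0.0501) and MAD2L1 and CERS5 without knockdown 1 alone (edgeR adjusted p = 0.0556 for each). FABP6, CD200R1, TDRD10, TNNT1, COTL1, ESYT3, NPTX2, RYR1, FZD6, SUSD5 and KIF15 each lost it without control 1 and without 2 to 7 other libraries. The number called was 19, 20, 16 and 28 without control 1, 2, 3 and 4, 77 without control 6, 16 and 31 without knockdown 1 and 3, and 79 without knockdown 4. It also depended on the test, with 349 genes called by DESeq2, 56 by limma-voom, and by edgeR 7 after libraries sharing a title number were summed and 28 with the title letter as a covariate, 26 of them among the 49. G3BP1, a stress granule protein named here after its values were seen, fell 1.52-fold to 203 ± 14.2 CPM (SD, n = 6, log2 fold change −0.60, SE 0.083, edgeR adjusted p = 0.0113). RN7SL2 and ABCA17P, also outside the rule, were called higher but share sequence with other copies or overlap other genes, so their reads may be split or shared.

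Targets that EWSR1-FLI1 activates were higher as a group in knock-down. Of 33 tested members 27 had a positive log2 fold change, with a median of 0.23 (camera adjusted p = 7.76e-05, adjusted p = 0.729 with an estimated correlation). At the preset correlation camera called 7 lists in all, against a mean of 8.57 in the other splits of the libraries. The neuropeptide CCK and the neuropeptide Y receptor NPY1R, at 41.3 ± 5.54 CPM in control and 73.3 ± 13.1 CPM in knock-down (SD, n = 6, edgeR adjusted p = 0.0151), were called over all genes, and 5 members when adjusted over the list alone. The call of NPY1R ended without control 1, 2 or 3 (edgeR adjusted p = 0.0523, 0.0531 and 0.0529) and that of CCK without control 3 (0.0523). ID2, an inhibitor of helix-loop-helix factors, and FCGRT, the neonatal Fc receptor, had log2 fold changes of 0.50 and 0.46 (edgeR adjusted p = 0.162 and 0.187). The mean of the list was higher by 0.26 on the log2 scale (exact permutation p = 0.00433, adjusted over 32 lists 0.139). Without control 6, knockdown 4 and knockdown 5, the libraries with the lowest correlation with the rest, the median of the list was 0.13. Of targets that EWSR1-FLI1 represses, 11 of 13 were positive with none called (camera adjusted p = 0.838), and NT5E and LOX were highest in knockdown 4. Without knockdown 4 the median of that list went from 0.19 to −0.13, with 5 of 13 positive. The transcripts of the fusion's own genes did not differ detectably, with log2 fold changes of 0.06 for FLI1 and −0.06 for EWSR1. The same held for the known targets NR0B1 (−0.14), NKX2-2 (0.37), SOX2 (−0.03), IGF1 (0.24), CCND1 (0.05) and EZH2 (0.09) and for AURKB (−0.07), with edgeR adjusted p values from 0.309 to 0.945.

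Developmental transcription factors that carry Polycomb marks in many cell types included 2 called rises and no called fall among 46 tested by edgeR, with 4 rises called by DESeq2 and 1, that of SIX2, by limma-voom. SIX2 rose as given above, and TWIST1, a basic helix-loop-helix factor of mesenchyme, rose from 47.1 ± 9.47 to 93.9 ± 27.2 CPM (SD, n = 6, edgeR adjusted p = 0.045), a call kept without control 6, knockdown 4 or knockdown 6 and lost without each other library (edgeR adjusted p from 0.0805 to 0.145). Adjusted over the list alone, 4 members were higher, with TFAP2B (log2 fold change 1.40, edgeR adjusted p = 0.0526) and MSX2 (0.78, 0.0999) beside these, and 30 of the 46 were positive (camera adjusted p = 0.173, and 0.0234 without knockdown 4). No HOX gene was called among 30 tested by edgeR, DESeq2 or limma-voom, 9 had an unadjusted p below 0.05, and 0 were called when adjusted over the list alone (camera adjusted p = 0.133, and 0.0412 without control 5). The 4 HOX genes with the smallest adjusted p were HOXC12, HOXC4, HOXC10 and HOXC11, with log2 fold changes from 0.43 to 0.84 (edgeR adjusted p from 0.171 to 0.224). All 9 tested members of the HOXC cluster were positive, against 2 of 5 in HOXA, 7 of 9 in HOXB and 2 of 7 in HOXD, a split looked at after the values were seen. Antisense genes overlap these clusters.

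Among 27 PRC1 subunits other than RNF2 13 were positive and edgeR, DESeq2 and limma-voom called none, with 5 at an unadjusted p below 0.05 (camera adjusted p = 0.956), with BMI1 at 55.1 ± 21.4 CPM in control and 66.1 ± 15.2 CPM in knock-down (SD, n = 6, edgeR adjusted p = 0.633). BMI1 was at 98.7 CPM in control 6 and at most 47.9 CPM in the other controls, and its log2 fold change was 0.26 with and 0.51 without control 6 (edgeR adjusted p = 0.113). PCGF2 had a log2 fold change of 0.27, and AUTS2, at low levels, one of 1.07 (edgeR adjusted p = 0.281 and 0.298). Among 12 PRC2 subunits 6 were positive and the same tools called none, with 1 at an unadjusted p below 0.05 (camera adjusted p = 0.956), with EPOP at 0.31 and SUZ12 at −0.14.

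Genes of the cytosolic ribosome lay higher in knock-down almost throughout, with 74 of 76 positive and a median log2 fold change of 0.30 (camera adjusted p = 2.86e-18, adjusted p = 0.729 with an estimated correlation). No ribosomal gene was called over all genes by edgeR, and 13 were when adjusted over the list alone. By edgeR 40 had an unadjusted p below 0.05, DESeq2 called 2 and limma-voom none. RPL13 was at 612 ± 75.9 CPM in control and 829 ± 101 CPM in knock-down (SD, n = 6, edgeR adjusted p = 0.114). Nuclear genes of oxidative phosphorylation were positive in 33 of 43, with a median of 0.13 (camera adjusted p = 0.00794, adjusted p = 0.729 with an estimated correlation). The camera call of this list ended without control 3 (adjusted p = 0.0969) or knockdown 2 (0.0602), and its median was 0.07 without control 3 and 0.21 without control 6. The mitochondrially encoded genes were positive in 7 of 15 and not called (camera adjusted p = 0.4, and 0.000819 without control 6, where all 15 were positive), and their share of the counts was 14.4% in control 6 against 4.65% to 7.08% in the other controls and 5.55% to 10.01% in knock-down.

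MHC class I genes, which present peptides to T cells, were positive in 11 of 13 with a median of 0.28 (camera adjusted p = 0.00346, adjusted p = 0.729 with an estimated correlation). The peptide transporter subunits TAP2 and TAP1 had log2 fold changes of 1.12 and 1.08, and the trimming peptidases ERAP1 and ERAP2 of 0.51 and 1.01 (edgeR adjusted p from 0.0623 to 0.203). No member was called over all genes by edgeR, 2 were by DESeq2 and 1 by limma-voom, and these 4 were by edgeR when adjusted over the list alone. Levels were low, with TAP2 at means of 2.32 CPM in control and 5.04 CPM in knock-down (n = 6 each, SE of the log2 fold change 0.236). The list mean was highest in knockdown 4, at 4.41 log2 CPM, and among controls in control 5, at 4.06. Host macrophage and leukocyte markers were highest in the same libraries, at 2.04 and 1.75 log2 CPM, and the median of the MHC list was 0.21 without knockdown 4 and 0.40 without control 5. Interferon response genes were positive in 19 of 25 with none called by edgeR (6 at an unadjusted p below 0.05, camera adjusted p = 0.133). That camera p was 0.0161 without control 5, 0.0186 without knockdown 2 and 0.044 without knockdown 6, and RSAD2 and PARP9 were highest in knockdown 4. The median of the list was 0.32 with all libraries and 0.17 without knockdown 4.

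The lists that lay lower in knock-down were DNA replication (26 of 35 negative, median −0.10, camera adjusted p = 0.00346), cholesterol synthesis (19 of 25 negative, −0.13, 0.00867) and glycolysis (14 of 18 negative, −0.09, 0.0378). Each had an adjusted p = 0.729 with an estimated correlation and no called member. FEN1, a flap endonuclease, had a log2 fold change of −0.35, the squalene synthase FDFT1 of −0.41 and the pyruvate kinase PKM of −0.38 (edgeR adjusted p = 0.217, 0.266 and 0.193), while the cholesterol gene PMVK was at 0.49. The calls of the replication, cholesterol and glycolysis lists ended without control 4 (camera adjusted p = 0.0502 for each). Those of cholesterol and glycolysis also ended without control 1 (0.0786 and 0.149) or knockdown 6 (0.0692 for each), and that of glycolysis without knockdown 3 or 5 (0.0642 and 0.17). The glycolysis median was −0.03 without control 1 or knockdown 5, −0.14 without control 5 or 6 and −0.17 without knockdown 4. That of cholesterol genes was −0.23 without control 6 and −0.26 without knockdown 3, and that of replication genes −0.06 without knockdown 4 and −0.03 without control 6, knockdown 4 and knockdown 5 (camera adjusted p = 0.0997). G2/M genes were negative in 22 of 30 with none called by edgeR (1 at an unadjusted p below 0.05, camera adjusted p = 0.222, and 0.013 without knockdown 2), among them KIF23 at −0.27 and MKI67 at −0.33.

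**Figure D3:**
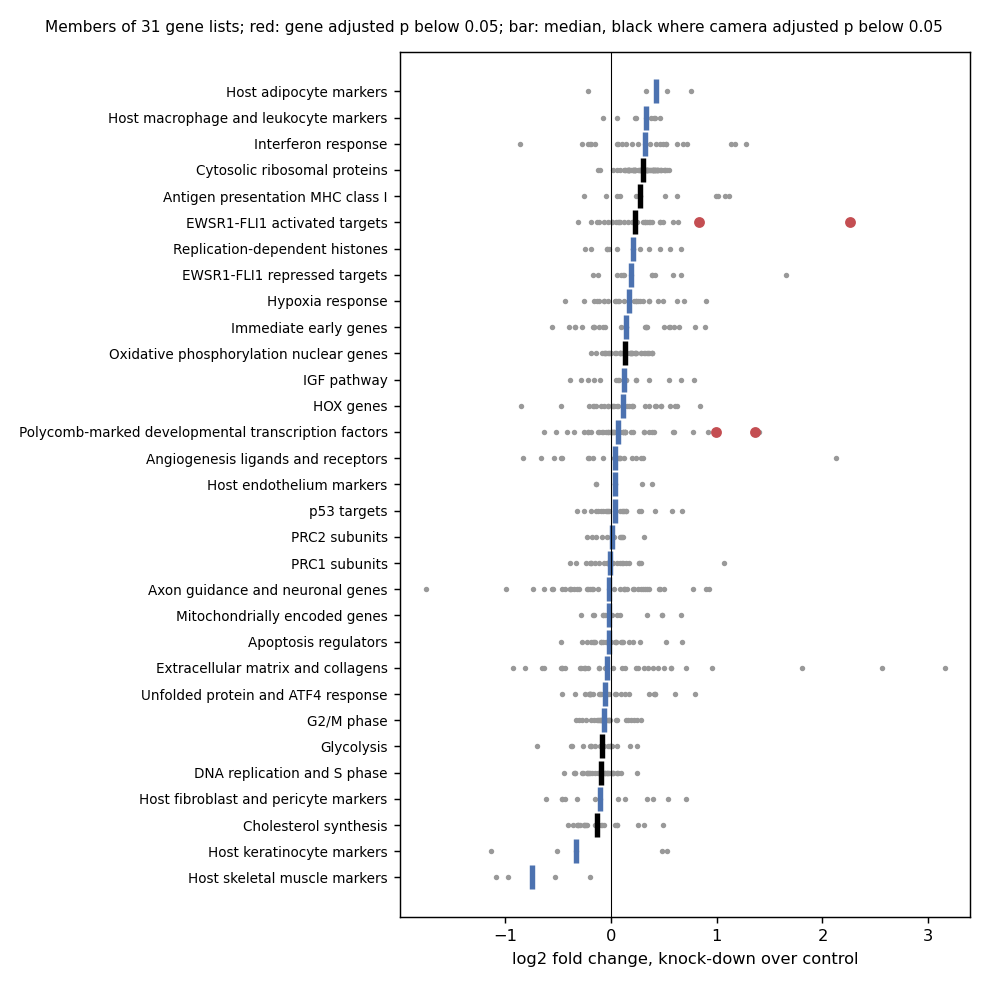
Log2 fold change in knock-down over control (x axis) of every tested member of 31 gene lists; grey points are members, red points are genes with an edgeR adjusted p below 0.05, and bars are list medians, black where the camera adjusted p was below 0.05 with a preset correlation. The 7 black medians lie between −0.13 and 0.30, and the red points are CCK, NPY1R, SIX2 and TWIST1.

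The remaining lists had no member called by edgeR and no camera call with all libraries. Of all 32 lists 30 held no gene called by edgeR, 21 of these held none called by DESeq2 and 29 none called by limma-voom. The p53 targets were positive in 11 of 22 (camera adjusted p = 0.886) with FAS at 0.67, and hypoxia genes in 18 of 26 (0.133) with ANGPTL4 at 0.69 and BNIP3 at 0.63. Genes of the unfolded protein and ATF4 response were positive in 11 of 29 (0.212), extracellular matrix genes in 17 of 35 (0.694) and axon guidance and neuronal genes in 20 of 41 (0.224). In these lists DCN, the proteoglycan decorin, was at 0.71 and ROBO2, a Slit receptor, at −0.63 (edgeR adjusted p = 0.0844 and 0.123). Angiogenesis genes were positive in 12 of 21 (0.332) with ANGPT1 at −0.83, the IGF pathway in 13 of 18 (0.704), apoptosis regulators in 12 of 26 (0.838), immediate early genes in 15 of 26 (0.4) and histones in 8 of 13 (0.248). Adjusted over the list alone, DCN, 2 apoptosis genes including FAS and 3 histone genes were higher, and ANGPT1 and 1 apoptosis gene lower. Without knockdown 4 the camera adjusted p was 0.0025 for the unfolded protein list, 0.0139 for extracellular matrix, 0.0234 for axon guidance, 0.0209 for angiogenesis and 0.0234 for histones. That of hypoxia genes was 0.0335 without control 1, 0.0454 without knockdown 1 and 0.0118 without knockdown 6, while its median of 0.17 went to 0.06 without knockdown 4 and to about 0.10 without control 2 or 5. The IGF pathway had a median of 0.13, and of −0.03 with 8 of 18 positive without knockdown 4. The median, the mean and the camera direction differed in sign in 8 lists, those of PRC1, the unfolded protein response, extracellular matrix, angiogenesis, apoptosis, mitochondrially encoded genes, host endothelium and host fibroblasts.

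Markers of host cells, counted on human genes, did not separate the groups. Tumour cells may contribute to these counts and host reads may fail to align, so the amount of host cells was not measured. The members tested ranged from 2 of 8 for blood to 13 of 15 for fibroblasts and pericytes. None of the 7 lists differed between groups by the exact permutation test of its mean (adjusted p from 0.587 to 0.989, no unadjusted p below 0.05), and camera called none (1 at an unadjusted p below 0.05). Macrophage and leukocyte markers had a median log2 fold change of 0.33 (camera adjusted p = 0.332), adipocyte markers of 0.43 (0.347), endothelial markers of 0.04 (0.905), fibroblast and pericyte markers of −0.10 (0.983), keratinocyte markers of −0.33 (0.347) and skeletal muscle markers of −0.75 (0.126). Only 2 blood markers were tested, HBB at 0.46 and ALAS2 at 0.61, too few for camera. Adjusted over the list alone, 1 keratinocyte marker was higher and 2 were lower, and DCN was higher among the fibroblast markers. The camera adjusted p of the muscle list, with CKM at −1.09 and ACTA1 at −0.97 over low group means, was 0.00228 without control 3, 0.0298 without control 6, and 0.0454, 0.0234 and 0.0407 without knockdown 1, 4 and 6, and that of macrophage markers was 0.0335 without control 5. Without knockdown 4 the median of the macrophage markers turned to −0.08 with 2 of 9 positive, and that of the adipocyte markers was 0.01, of the keratinocyte markers −0.17 and of the fibroblast markers −0.33. The fibroblast median was 0.05 without control 5, and the muscle median −0.45 without control 4, −1.19 without control 3 and −1.34 without knockdown 6. That of the endothelial markers was 0.20 without control 5 and −0.05 without control 2.

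Variation between libraries of 1 group was about as large as that between groups. The mean distance between libraries was 0.615 within and 0.652 between groups (exact permutation p = 0.0844). The first principal component held 36.8% of the variance and did not separate the groups (exact permutation p = 0.26), the second held 19.9% (p = 0.552 by the same exact test), and the third held 11.3% and did (exact permutation p = 0.00216). Genes at the high end of the first component included SDC2, SAA1, SFRP2, MMP1, PTX3 and TGFBI, and those at the low end DLK1 and VWDE. All of these are outside the naming rule. The lowest median correlations with the other libraries were 0.955 for knockdown 4, 0.966 for control 6 and 0.967 for knockdown 5. Libraries that share a title number were correlated at 0.993 and 0.985 in control and 0.944 and 0.967 in knock-down, and their mean distance was 0.626 against 0.613 for other pairs of a group. By chi-square per degree of freedom the control pairs were at 12.05, the lowest of all pairs, and 21.8, and the knock-down pairs at 83.63 and 125.11. Without control 6, knockdown 4 and knockdown 5, an alternative chosen after seeing the data, edgeR called 59 genes higher and 49 lower, 42 of them among the 49 called with all libraries. By chromosome, camera called 10 and 19 higher (median log2 fold change 0.08 and 0.09) and 3 and 15 lower (−0.08 and −0.09), with adjusted p values from 0.00163 to 0.0372 and from 0.353 to 0.779 with an estimated correlation.

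**Figure D4:**
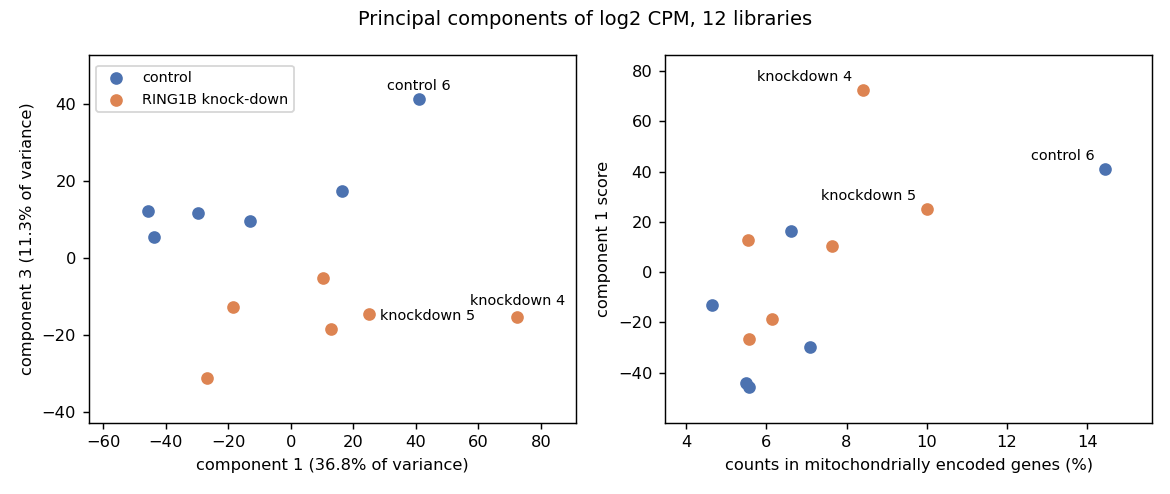
Left, scores of principal components 1 (x axis) and 3 (y axis) of log2 CPM, with 36.8% and 11.3% of the variance. Right, the percentage of counts in mitochondrially encoded genes (x axis) against the first component; each point is 1 of 6 control or 6 RING1B knock-down libraries, and control 6 stands at 14.4% of counts.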

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

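All tests of the heptamer rest on data that gave it, and its share among fallen genes, the 3′ UTR length tests, base composition, its choice in other libraries and all counts over other splits were tests chosen only after the result was seen.

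In 35 of 392 groups of 6 libraries, 1 library lay far from the other 5, by the gap to its nearest neighbour as a share of the whole range, where chance gives about 1 in 20 groups, or 19.6. Control 6 was that library in 15 groups and knockdown 4 in 11, against 3 for control 5, 2 for knockdown 6 and 1 each for control 3 and knockdown 1, 3 and 5. Control 6 had 14.45% of counts in mitochondrially encoded genes (other controls 4.65% to 7.08%), 24918 genes with a count (26677 to 27456) and a score of 41.17 on principal component 3 (5.41 to 17.33). Its mean log2 CPM of mitochondrially encoded genes was 12.62 (10.80 to 11.44). The genes were MT-ND5 at 3625 CPM (1141 to 2038), MT-ND6 at 637.7 (187.8 to 312.6), MT-RNR1 at 1469 (377.9 to 650.3) and MT-RNR2 at 10670 (3229 to 4455). Also apart in control 6 were MAD2L1 at 136.7 CPM (79.15 to 90.54), BMI1 at 98.69 (43.74 to 47.93), NPY1R at 51.58 (34.81 to 40.93), SESN1 at 23.78 (20.01 to 21.13) and HIST1H2AC at 39.61 (29.59 to 31.73). PFKP at 177.4 CPM (239.6 to 270.1) and FLT4 at 12.52 (15.61 to 16.79) were lower there.

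Knockdown 4 stood apart by a mean log2 CPM of 4.787 for EWSR1-FLI1 repressed targets (other knock-down libraries 2.701 to 3.209) and of 7.031 for the unfolded protein and ATF4 response (6.346 to 6.570). NT5E was at 16.73 CPM (0.277 to 1.128), LOX at 27.89 (7.289 to 14.40), FLT1 at 10.13 (0.3152 to 0.8352) and JAG1 at 53.69 (27.60 to 34.63). RSAD2 was at 5.45 CPM (0.7193 to 2.453), PARP9 at 11.97 (1.261 to 3.442), and the leukocyte and adipocyte markers CTSS at 10.60 (2.294 to 5.381), SPI1 at 7.75 (1.347 to 3.173) and CFD at 4.641 (1.576 to 2.666). In control 5, SPI1 was at 6.444 CPM (0.9484 to 2.554), CFD at 2.387 (1.037 to 1.424) and KIF15 at 117.3 (148.5 to 163.7). Single values apart were HIST1H2BD at 17.94 CPM in control 3 (21.56 to 23.47), SLC16A3 at 64.81 in knockdown 1 (23.48 to 37.34), SCMH1 at 60.81 in knockdown 3 (38.96 to 46.77), PNPLA2 at 32.41 in knockdown 5 (48.61 to 58.00), and PHC3 at 39.52 (25.08 to 28.65) and CKM at 1.458 (0.08516 to 0.5429) in knockdown 6.

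Many genes that fell with RNF2 carry the heptamer GAAGCAA in the 3′ UTR, 9 of 19 called-lower coding genes against 13.8% of the others (Fisher exact p = 0.000451). It was picked as the lowest t (−8.08) of 16256 heptamers on these same genes and libraries, so that p, the chance of as many at like 3′ UTR length (0.00153), the lowest t of other orders of its bases (−1.97) and its first rank in 95 of 100 random parts of the genes and rank of at worst 2 in parts of the libraries decide nothing. Shifts over all coding genes were small. The median log2 fold change was −0.052 with GAAGCAAA in the 3′ UTR (57.8% negative) and −0.009 with GAAGCAA but not GAAGCAAA there (51.9%). It was 0.011 with only AAGCAA there (47.5%) and 0.045 with none of these in the transcript (41.3%). Genes with GAAGCAA only outside the 3′ UTR were at −0.032 (56.0%), so the shift was not confined to the 3′ UTR. Each t is already adjusted for GC content, so other orders of the bases cannot test that. Base composition beyond GC content is argued against by a median t of 0.34 over 93 other orders. Long 3′ UTRs did not put most heptamers in many of these genes, since a median of 3 of the 19 carry each of 2112 others found in as many genes. Genes of like 3′ UTR length already gave an expected 3.5 for GAAGCAA. Typical heptamers cannot show what length does for 1 picked as the most extreme, so this does not decide. Chosen in replicates 4 to 6 alone, GAAGCAA ranked 2 in replicates 1 to 3. TGCTGCT, the lowest in replicates 1 to 3, ranked 3907 in the others. A t as large as 8.08 arose in 12 of 100 splits (highest other 9.75), so chance stays open. The lead over the next was 1.87 (highest other 1.83, 1 of 100 splits). That 1.83 was the lead of GAAGCAA itself in a split sharing 5 control libraries with the real one. The lead was taken up because GAAGCAA was seen to lead, so it cannot exclude chance. A seed match of the silencing RNA, whose sequence is not given in the sources used here, is a candidate explanation that stays open, as does an effect of RING1B loss; RNF2 carries GAAGCAA once, in its coding part, and of the 10 other falls NEFH and DGKK carry it outside the 3′ UTR.

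Targets that EWSR1-FLI1 activates had a median log2 fold change of 0.23 in knock-down. None of 10000 lists matched on expression and transcript length had one as high (share 0.0001, the smallest these draws can give; highest 0.155). No single library carried it, since the lowest median without any library was 0.164 and the camera adjusted p stayed at or below 0.00208. Nor did a few members, since 22 of the 28 not called over the list alone were positive (binomial p = 0.0039, for genes that are not independent). The correlation between its genes stays open, with camera adjusted p = 0.729 when estimated. A seed match and an effect of RING1B loss stay open too, neither tested for this list. As many lists as the 7 seen were called in 68 of 100 splits (mean of the others 8.57, highest 16). Chance is not excluded for that number, and a camera call at the preset correlation does not by itself set the real grouping apart.

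Ribosomal protein genes had a median log2 fold change of 0.30. Expression level and transcript length alone were argued against by matched lists (share as high 0.0001, the smallest 10000 draws can give, with a highest of 0.119). The members of those lists were drawn independently, while the ribosomal genes had an estimated correlation of 0.516. That share is therefore no measure of chance for genes that vary together. The correlation between these genes stays open, with camera adjusted p = 0.729 when estimated. The mitochondrial share of counts, taken as a sign of RNA quality, was not related to the list mean over 12 libraries beyond chance (Spearman rho 0.462, permutation p = 0.132, adjusted 0.198 over 3 relations; Pearson r 0.558, permutation p = 0.0532, and 0.597 without control 6 and knockdown 5). With that share as a covariate the difference on the log2 scale was 0.29 against 0.28 without. This decides little, because the groups were alike in mean share only through control 6, at 14.45%. The other controls lay at 4.65% to 7.08% and knock-down at 5.55% to 10.01%, so the covariate could hardly move the difference. Within groups r was 0.799 in control, where rho was 0.086, and 0.872 in knock-down, where rho was 0.829, so a relation inside groups may remain. Other signs of RNA quality and growth rate of the tumours were not tested, and an effect of RING1B loss stays open as untested.

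The number of called genes was above that of all 99 other splits drawn. The real grouping called 49 genes against at most 1 in another split (1 of 100 splits as large). It called 29 higher (1 of 100) and 20 lower (1 of 100), against at most 1 in the larger direction of another split. At 2-fold or more it called 25 against 1 (1 of 100). Chance is excluded for these counts only as far as the libraries are independent. The real grouping keeps libraries that share a title number together, while other splits can part them, so an effect tied to the number is not excluded. Counts summed by title number left 2 genes higher and 5 lower. Chromosomes were called as often in 52 of 100 splits (4 seen, highest other 12), so chance is not excluded for them. Other splits gave up to 4499 genes at an unadjusted p below 0.05, and several exceeded the 2091 of the real one. This points to a structure of the samples other than the groups.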

How the results depend on the processing

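The fit without control 6, knockdown 4 and knockdown 5, and those without mitochondrially encoded genes or genes with GAAGCAA, were chosen only after the result was seen. RNF2 stayed lower and called in every setting in which it was tested, with log2 fold changes from −1.53 to −1.35 without each library. No called gene or list changed direction. Of 32 lists, 13 had a median that changed sign without at least 1 library, none of them called. Without knockdown 4 EWSR1-FLI1 repressed targets went from 0.19 to −0.13 (−0.27 without all 3 libraries) and macrophage markers from 0.33 to −0.08, and without control 6 mitochondrially encoded genes went from −0.02 to 0.37. Without the 3 libraries the hypoxia list had a median of 0.00 and the interferon list 0.13. The counts of called genes kept within 1.5 times under RLE or upper quartile factors, library size, no filter, a CPM filter, limma-voom and removal of mitochondrially encoded genes. In the order higher, lower, higher at least 2-fold and lower at least 2-fold, the 29, 20, 18 and 7 genes became 208, 141, 101 and 36 with DESeq2, all 49 among them, and 319, 181, 121 and 43 with limma-voom quality weights. They became 52, 39, 30 and 12 with the title number as a random effect, and 2, 5, 2 and 3 with counts summed by title number, which leaves fewer samples. The fitted correlation within a title number was −0.125. The higher counts of that fit are therefore no allowance for libraries of a number being alike. With 1 surrogate variable they were 64, 44, 32 and 17, and at an adjusted p of 0.01, a stricter limit, 0, 3, 0 and 2.

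With the title letter as a covariate 12 genes were higher, 9 of them at least 2-fold, and 26 of the 49 calls were kept among 28. Control holds 2 libraries with letter D and 4 with E, and knock-down 4 and 2. The host marker mean gave 64, 32 and 31 for the first 3 counts, and centred within group 60, 31 and 31. Without control 6, knockdown 4 and knockdown 5 the counts were 59 higher, 49 lower and 19 lower at least 2-fold, and without genes carrying GAAGCAA 11 lower and 20 higher, where 9 called-lower genes and CCK were no longer tested. Leaving out each library gave 6 to 48 higher, 9 to 36 lower, 5 to 25 higher and 4 to 15 lower at least 2-fold. The cause was not tested except where stated.

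The 7 gene lists called by camera were 0 with an estimated correlation (1 unadjusted), 0 by fry's directional test (3 unadjusted), and from 4 without control 4 to 14 without knockdown 4. Fry's mixed test, for change in either direction, called 4: EWSR1-FLI1 activated targets and HOX genes (adjusted p = 0.0172 each by fry), and Polycomb-marked factors and MHC class I (0.0208 each). The 4 chromosomes called were 0 with an estimated correlation (2 unadjusted). Of list results under alternatives, 529 kept their side of the threshold, 29 lost a call and 29 gained one, and of named gene results 4440 kept it, 147 lost a call and 60 gained one. No paired analysis was possible because no title number was shared across groups. Depth limits low genes: 3 counts correspond to 0.112 to 0.126 CPM.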

Other observations

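The split of HOX genes by cluster and the relation with the mitochondrial share were chosen only after the result was seen. The HOXC genes had a median log2 fold change of 0.48 with all 9 positive, against −0.02 in HOXA, 0.05 in HOXB and −0.15 in HOXD, and none was called by edgeR, DESeq2 or limma-voom (9 of all 30 HOX genes at an unadjusted p below 0.05 by edgeR). The first principal component and the mitochondrial share of counts had a Pearson r of 0.633 (permutation p = 0.0255, adjusted 0.0674 over 3 relations) and a Spearman rho of 0.65 (permutation p = 0.0253, adjusted 0.0759), a relation that did not pass the correction, and r was 0.674 without control 6 and knockdown 5.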
